A study of Mus musculus with 6 samples.

How the data were processed

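Gene expression was measured on 6 one-colour Agilent mouse arrays, one per sample, from embryonic kidneys at E14.5. The titles and the design text give 2 lines with floxed Sall1. In the Six2Cre line, where the deletion was directed to nephron progenitors, there were 2 control arrays (replicates 5 and 2) and 2 knockout arrays (replicates 7 and 9). In the tamoxifen-inducible CreER line, there was 1 control array (replicate 2) and 1 knockout array (replicate 5), with tamoxifen at E12.5 and kidneys taken 48 hours later. The genotype is stated for each sample, whereas the line was read from the style of the titles together with the design text. One description mentions tamoxifen for all 6 samples, so that whether the Six2Cre mice also received it is open. Before the replicate number, the CreER control is titled wt/flox and the CreER knockout CreER/flox. In that pair CreER is thus named for the knockout alone, so its presence cannot be told apart from loss of Sall1. The labels do not say whether the Six2Cre controls carried Cre, which part of Sall1 was floxed, or whether each array came from a separate embryo. The p values of single genes therefore measure the spread between these samples.

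The authors labelled 0.25 ug of RNA per sample with Cy3 and extracted the scans with Feature Extraction 10.5.1.1. Per the file headers, the processed signal is an intensity on a linear scale, background-subtracted and detrended within each array and not normalized between arrays. The deposited series table holds the same intensity: for probes with a single spot, 100% of its values lay within a relative tolerance of 0.001 of the array's processed signal. Its column medians were 235.24, 217.72, 202.6, 216.94, 218.29 and 187.02 for Six2Cre control 5, Six2Cre knockout 7, Six2Cre control 2, Six2Cre knockout 9, CreER control 2 and CreER knockout 5. Per the file headers, the raw spot and local background columns hold median pixel intensity. Per the labels, total RNA was extracted with Trizol and its quality was monitored on a Bioanalyzer; the resulting quality values, and how many kidneys made up a sample, are not given in the sources used here.

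Six2Cre control 5 and Six2Cre knockout 7 were on slide 1 and the other 4 arrays were on slide 2, with scanning batches that followed the slides. Each slide held a Six2Cre control and a Six2Cre knockout, so the slide could be fitted as a block and each pair read within its slide. Spots of a probe were averaged. Of 41174 non-control probes, 40987 had no outlier flag on any array. Probes were named by matching their RefSeq accession, without its version, to a mouse reference annotation; 25097 probes took the names of 17305 genes. No positions are given, because the array's design and the annotation use different genome builds. The log2 processed signal minus the array's 75th percentile was the value analysed. A gene was represented by its probe with the highest mean signal over the 6 arrays. Features were kept when well above background on at least 2 of the 6 arrays, which left 26395 (15235 named genes and 11160 transcripts without a matched name). Of 5480 genes with more than 1 kept probe, 1543 had probes of opposite sign in the Six2Cre comparison, 20 of them by more than 0.5 log2 units each way; Dazl was the only gene named here among these 20.

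One limma fit (limma 3.58.1 in R 4.3.3, with data.table version 1.17.8) of the 4 groups gave the Six2Cre contrast and the difference between lines, with lmFit and eBayes, two-sided tests and Benjamini-Hochberg adjustment at 0.05. The lone CreER arrays were assumed to vary like the Six2Cre groups in the difference between lines. A second fit took genotype over all 6 arrays with line and slide as covariates. The CreER arrays alone allow no test, so genes with a difference of at least 2-fold were counted among those well above background on at least 1 of the 2 arrays, and the same count between other pairs of arrays stands beside it. Where a gene was well above background on no array of a group, each of that group's values below the array's dimmest well-above-background signal was raised to it, and the fold is a lower bound, written "at least". Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

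The 26 gene lists and the tests were fixed before the data were examined. The lists cover nephron progenitors, early nephrons, podocytes, proximal tubule, loop and distal tubule, ureteric bud tip, ureteric trunk and collecting duct, stroma, endothelium, erythroid cells, macrophages, neural crest with neurons and glia, adrenal, gonad and germ cells, muscle, Y-linked genes with Xist, p53 and apoptosis, proliferation, immediate early stress genes, hypoxia and glycolysis, Wnt targets, the Notch pathway, FGF targets, BMP and TGF-beta, Sall proteins with the NuRD complex, and posterior Hox genes. Of the 446 measured genes in them, 28 stand in more than 1 list. Lists were tested in the Six2Cre contrast with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 26 lists. With an estimated correlation, camera takes its p value on the fit's 2 residual degrees of freedom. At the preset correlation it uses degrees of freedom set by the number of genes. In the CreER arrays a list's median was set against 10000 random lists matched on mean signal. Named genes are the 4 Sall genes; in each direction of the Six2Cre contrast and of the contrast over both lines, the 10 largest changes among genes that passed with all knockout arrays beyond all control arrays of their line, filled up by lowest unadjusted p where fewer passed; the 10 largest CreER differences in each direction among genes well above background on both arrays; and of each list its passing members, or the 4 of largest change where none passed. Accession-like and clone names were passed over.

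The tests were tried on simulated data, 5 simulations of 26395 genes with 200 changed genes each. Noise was drawn with each gene's spread as moderated by eBayes, so recovery may be overstated. With slide differences of the size seen here, the fit of the 4 groups recovered 0% of 8-fold changes. The fit with slide as a block recovered 98.2% of 4-fold and 20.5% of 2-fold changes, with a mean of 49.6 false calls. With eBayes trend and robust added to the block, the mean was 43.4 false calls. The fit over both lines recovered 98.2% of 4-fold changes. Alternatives tried were normexp background correction with an offset of 50, quantile normalization, no filter or a filter on all 6 arrays, the mean of a gene's probes, the series table's values, eBayes with trend and robust, adjusted p under 0.1, slide as a block, the 4 Six2Cre arrays alone, other covariates, and leaving out each array. Normexp used median spot and background signal in place of the planned mean spot signal, which the files lack. Combinations of the slide block with another choice were added after the data had been seen. No sample was left out.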

Results

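Transcript levels were compared between Sall1 knockout and control kidneys of mouse embryos at E14.5. Sall1 is a zinc finger transcription factor of the nephron progenitors, the cap mesenchyme cells from which nephrons form. The Six2Cre line had 2 control and 2 knockout arrays, and the inducible CreER line had 1 of each. The share of probes well above background was 80.4% on Six2Cre control 5, 79.9% on Six2Cre knockout 7, 80.1% on Six2Cre control 2, 82.9% on Six2Cre knockout 9, 82.2% on CreER control 2 and 71.6% on CreER knockout 5. The SD of the negative control spots was 4.01 on CreER knockout 5 and between 1.46 and 1.61 on the other 5 arrays. Pearson r between arrays, across genes, which are not independent replicates, ran from 0.969 to 0.993. The number of arrays limits the precision: Six2Cre values are means of n = 2 arrays per group with SE from limma, and CreER values are differences of single arrays without an error. Log2 values are knockout minus control unless stated otherwise.

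The targeted gene was the first point of comparison. Sall1 was 2.38-fold lower in Six2Cre knockouts (log2 fold change -1.25, SE 0.38, limma adjusted p = 0.595), with -1.26 in the slide 1 pair and -1.23 in the slide 2 pair. It was 6.87-fold lower on the CreER knockout array (-2.78). The array carries 1 Sall1 probe, whose position relative to the floxed part is not given in the sources used here. Its signal stayed well above background on all 6 arrays. Of the related genes, Sall3 was 5.70-fold lower in Six2Cre knockouts (-2.51, SE 0.25, adjusted p = 0.0989) and -0.69 in the CreER pair. Sall2 differed by -0.20 (SE 0.26) and Sall4 by 0.24 (SE 0.32) in the Six2Cre line. In the slide block with eBayes trend and robust, chosen after the data had been seen, the adjusted p of Sall1 was 0.0249 and that of Sall3 0.00441. The sign of the Sall4 value turned when 1 array was left out, and the Sall2 value then ran from -0.32 to -0.0757. In the list of Sall proteins with NuRD, a chromatin remodelling complex, 10 of 16 members were lower, with a median of -0.16 (camera adjusted p = 0.0274; adjusted p = 0.284 with an estimated correlation). The call was also lost when any of the 4 Six2Cre arrays was left out (adjusted p from 0.0636 to 0.140). Sall3 alone passed when adjusted over the list alone; Chd4 (-0.58) and Hdac2 (0.46) were the complex members of largest change.

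The Six2Cre comparison asks which transcripts differ after deletion of Sall1 in nephron progenitors. Single transcripts of nephron segments and progenitors had many-fold lower signal in knockout kidneys, while the medians of their lists ranged from -0.34 to -1.60. Slc12a1, the sodium-potassium-chloride cotransporter of the loop of Henle, was 73.7-fold lower (log2 fold change -6.20, SE 0.77). Slc34a1, the sodium-phosphate cotransporter of the proximal tubule, was 52.3-fold lower (-5.71, SE 0.42), and Kcnj1, the potassium channel of the thick ascending limb, was 34.6-fold lower (-5.11, SE 0.33). Cited1, a marker of the least committed progenitors, was 17.9-fold lower (-4.16, SE 0.39). The adjusted p of these 4 genes ran from 0.0828 to 0.138 and none passed over all genes tested.

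In the proximal tubule list, 23 of 28 measured members were lower, with a median of -1.60 (-1.60 in the slide 1 pair and -1.69 in the slide 2 pair). Camera gave an adjusted p of 1.36e-24, and the call was lost with an estimated correlation (adjusted p = 0.125). No member passed over all genes tested, and 19 were lower when adjusted over the list alone. Among them were Spp2 (22.5-fold lower), Hnf4a, a transcription factor of proximal tubule differentiation (10.3-fold lower, log2 fold change -3.36, SE 0.41), and Slc39a5, a zinc transporter (-3.33, SE 0.47). The loop and distal tubule list had 14 of 17 members lower, with a median of -1.19 (-1.30 and -1.09 within the slides), and 8 lower when adjusted over the list alone. Its camera adjusted p was 5.33e-15 (adjusted p = 0.125 with an estimated correlation). Besides Slc12a1 and Kcnj1 these included Sim2, a transcription factor (11.3-fold lower), and Umod, which encodes uromodulin (8.10-fold lower).

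In the early nephron list, of genes of the renal vesicle and S-shaped body, 25 of 28 members were lower, with a median of -0.91 (-0.90 and -0.76 within the slides; camera adjusted p = 1.41e-14; adjusted p = 0.125 with an estimated correlation). Of these, 9 were lower when adjusted over the list alone, among them the patterning factors Irx2 (-3.16, SE 0.36) and Irx1 (-2.54, SE 0.30) and the Notch target Hes5 (-2.08, SE 0.27). The nephron progenitor list had 27 of 29 members lower, with a median of -0.70 (-0.80 and -0.82 within the slides; camera adjusted p = 1.72e-15; adjusted p = 0.125 with an estimated correlation). Adjusted over the list alone, 5 were lower. Besides Cited1 they included Traf1 (4.005-fold lower), Six2, the factor that keeps progenitors undifferentiated (3.02-fold lower, -1.59, SE 0.27), and Spock2 (2.88-fold lower). Sall1 itself is a member of this list. In the podocyte list 17 of 23 members were lower, with a median of -0.34 (-0.40 and -0.26 within the slides; camera adjusted p = 0.000136; adjusted p = 0.279 with an estimated correlation), and 3 passed when adjusted over the list alone. Without Six2Cre knockout 9 the median was -0.66. One of them, Clic5, was 2.70-fold lower. Nphs1, which encodes nephrin, was 11.4-fold lower (26.1-fold and 4.98-fold within the slides) and Ptpro 3.98-fold lower, both short of the threshold over the list alone.

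**Figure D1:**
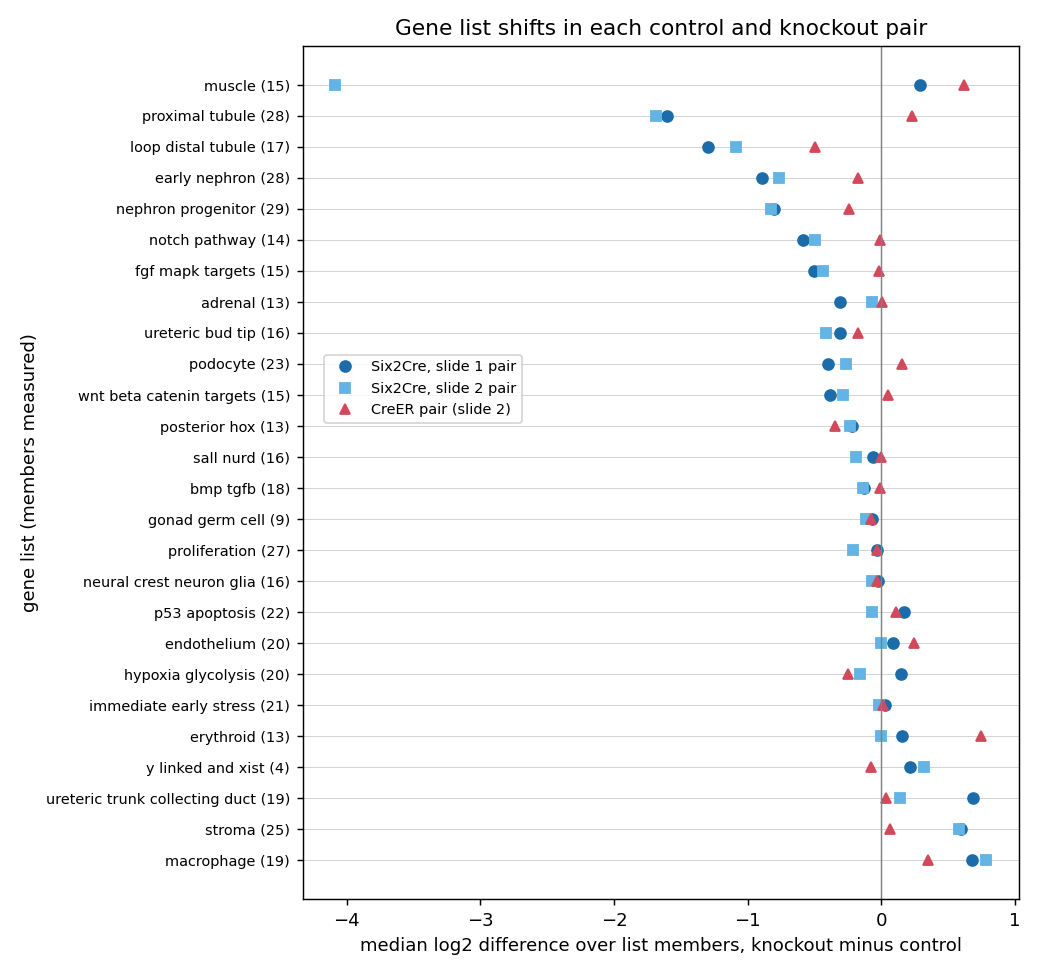
Median log2 difference (knockout minus control) over the measured members of each of the 26 gene lists, for the Six2Cre pair on slide 1 (circles), the Six2Cre pair on slide 2 (squares) and the CreER pair (triangles); the number of measured members is in brackets. The proximal tubule median was -1.60 and -1.69 in the Six2Cre pairs and 0.23 in the CreER pair, whereas the muscle median was -4.08 in the slide 2 Six2Cre pair and 0.29 in the slide 1 pair.

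Of the signalling lists, Notch, FGF and Wnt passed at the preset correlation with medians below 0 in Six2Cre knockouts, and of these only Notch also passed with fry. They are not separate from the other lists. Of their measured members, 5 of 14 for Notch, 7 of 15 for FGF and 3 of 15 for Wnt also stand in another list. Hes5 is also in the early nephron list and Cited1 in the nephron progenitor list. The Notch pathway list had a median of -0.58, with 12 of 14 members lower (camera adjusted p = 1.28e-06; adjusted p = 0.140 with an estimated correlation); its member Hes5 passed when adjusted over the list alone, and the ligand Dll1 was -1.56 (SE 0.35). The FGF target list had a median of -0.53, with 14 of 15 members lower (camera adjusted p = 7.01e-05; adjusted p = 0.196 with an estimated correlation). None passed when adjusted over the list alone; Etv4 was -1.20 (SE 0.51), Fgf8, a ligand of the renal vesicle, -1.04 (SE 0.24) and Etv5 -0.71 (SE 0.28). The Wnt target list had a median of -0.27, with 13 of 15 members lower (camera adjusted p = 5.86e-05; adjusted p = 0.279 with an estimated correlation), and without Six2Cre knockout 9 the median was -0.57. Cited1, the Wnt antagonist Dkk1 (3.31-fold lower) and the receptor Lgr5 (2.12-fold lower) passed when adjusted over the list alone. In the ureteric bud tip list 13 of 16 members were lower, with a median of -0.35 (camera adjusted p = 0.000972; adjusted p = 0.370 with an estimated correlation). The call was lost without Six2Cre knockout 9 (median -0.18, adjusted p = 0.212). Only Sox8 passed when adjusted over the list alone (-1.70, SE 0.27), and Tmem59l was -0.92 (SE 0.26) and Adamts18 1.26 (SE 0.55).

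Markers of stroma and of macrophages were higher in Six2Cre knockouts. The stroma list had 20 of 25 members higher, with a median of 0.60 (0.60 and 0.58 within the slides; camera adjusted p = 7.41e-08; adjusted p = 0.127 with an estimated correlation). Its largest values were those of Ntn1, which encodes netrin 1 (4.102-fold higher, 2.04, SE 0.54), the proteoglycan gene Lum (2.52-fold higher), Smoc2 (2.47-fold higher) and Foxd1, the marker of cortical stromal progenitors (2.42-fold higher). The macrophage list had 17 of 19 members higher, all 17 in both pairs, with a median of 0.70 (0.67 and 0.78 within the slides; camera adjusted p = 1.06e-09; adjusted p = 0.274 with an estimated correlation). Cd14 was 2.07-fold, the leukocyte gene Ptprc 1.83-fold, Pf4 1.77-fold and Ccl4 1.75-fold higher. No member of either list passed when adjusted over the list alone. The ureteric trunk and collecting duct list had a median of 0.50, with 13 of 19 members higher and 0.69 against 0.14 within the slides (camera adjusted p = 0.0127; adjusted p = 0.522 with an estimated correlation). The call was lost without Six2Cre control 5 (0.23, adjusted p = 0.470) and without Six2Cre knockout 7 (0.32, adjusted p = 0.369). Krt19, a keratin, was 1.09 (SE 0.32), Upk1b 1.20 (SE 0.60) and Foxi1, a factor of intercalated cells, -1.59 (SE 0.57).

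The muscle list set 1 array apart. On Six2Cre control 2 its members lay a median of 14.6-fold above each gene's own median on the other 5 arrays, and all 15 members were at least 2-fold above it. Its Six2Cre median was -1.65 (camera adjusted p = 1.75e-06; adjusted p = 0.505 with an estimated correlation), with -4.08 in the slide 2 pair and 0.29 in the slide 1 pair. Without Six2Cre control 2 it was 0.0348 (adjusted p = 0.953). Ttn, a sarcomere protein gene, was -3.86 (SE 1.67), Myog -2.82 (SE 1.18), Myh3 -2.77 (SE 2.09) and Tnnt2 -2.29 (SE 1.29).

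The other 12 lists did not pass in the Six2Cre comparison. Medians and camera adjusted p were -0.43 and 0.0864 for adrenal, -0.23 and 0.0713 for posterior Hox, -0.12 and 0.0539 for proliferation, and -0.16 and 0.130 for BMP and TGF-beta. Proliferation passed with slide as a block (adjusted p = 0.0334), with quantile normalization (0.0138) and without Six2Cre knockout 7 (0.0106), and adrenal passed without Six2Cre control 2 (0.0135) and without Six2Cre knockout 7 (0.0209). For the list of Y-linked genes with Xist the values were 0.27 and 0.355, over 4 measured Y-linked genes without Xist, which was not among them. The values were -0.02 and 0.385 for neural crest with neurons and glia, 0.12 and 0.548 for erythroid, and 0.08 and 0.744 for immediate early stress genes. They were 0.01 and 0.744 for p53 and apoptosis, -0.15 and 0.796 for gonad and germ cells, 0.03 and 0.796 for hypoxia and glycolysis, and 0.02 and 0.817 for endothelium. Within them, Nr0b1, a nuclear receptor (4.64-fold higher), and Elavl4, a neuronal RNA-binding protein (3.28-fold lower), passed when adjusted over the list alone. Hoxb9 was -1.09 (SE 0.25), Tgfb2 1.30 (SE 0.29) and Egr2 -1.31 (SE 0.25).

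The genes of lowest p in the Six2Cre comparison included others besides Slc34a1 and Kcnj1. Amn, which encodes amnionless of the endocytic receptor complex, was 13.9-fold lower (-3.80, SE 0.27). The ascorbate transporter Slc23a1 was at least 13.9-fold lower, the brush border protease Mep1b at least 8.81-fold, the ectonucleotidase Entpd8 16.4-fold and Lamp5 at least 34.7-fold. C8a was at least 7.84-fold, Cyp4a31 at least 3.55-fold and the orphan nuclear receptor Nr2e1 at least 2.18-fold lower. Among those higher in knockouts were Csf3, which encodes the granulocyte colony-stimulating factor (at least 11.3-fold), Sult1e1, an estrogen sulfotransferase (10.9-fold), Efcab3 (7.62-fold), Ptger3, a prostaglandin E2 receptor (5.10-fold), Pdzph1 (4.92-fold), Dipk1c (4.67-fold), Kera, which encodes keratocan (4.14-fold), Speer3 (at least 1.74-fold) and Gpr149 (at least 1.46-fold). The adjusted p of all 10 lower genes was 0.0828, and that of the higher genes named ran from 0.0828 to 0.123, so none of these passed.

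Over all 26395 features, limma called 0 higher and 0 lower in Six2Cre knockouts; at an unadjusted p under 0.05 there were 961 higher and 708 lower, where chance gives 1320 in all. With slide as a block the counts were again 0 and 0, with 1876 and 1197 at an unadjusted p under 0.05. The block together with eBayes trend and robust, chosen after the data had been seen, gave 325 higher and 336 lower, and the block with normexp gave 225 and 262, with 472 genes shared by the 661 and the 487 calls. Of the 122 genes named for the Six2Cre comparison, 60 passed in the first of these settings, with adjusted p of 0.00106 for Slc34a1, 0.00139 for Slc12a1, 0.00172 for Kcnj1 and 0.000479 for Cited1. In the simulations that setting gave a mean of 43.4 false calls beside 200 changed genes, so its adjusted p may be too low. In both slide pairs, 441 features were at least 2-fold lower and 412 at least 2-fold higher, against 66.0 and 44.4 if the pairs were independent. That expectation takes all features as equally variable, whereas more variable features would pass in both pairs more often. Overlap in opposite directions was not counted, so the excess alone does not show an effect of genotype. On simulated data with the slide differences kept, the test without the block recovered 0% of 8-fold changes, so its 0 does not count against changes of that size. The test with the block recovered 98.2% of 4-fold and 100% of 8-fold simulated changes, yet also called 0 on these arrays (limma, lowest adjusted p = 0.0822). It did not call Cited1, which was -4.05 in the slide 1 pair and -4.28 in the slide 2 pair. Simulated noise took each gene's spread as moderated by eBayes, which makes genes more alike and may overstate recovery. The 0 with the block therefore does not show that large changes are absent. All list calls rest on camera at the preset correlation, whose p values are taken over genes and do not measure the spread between arrays. With an estimated correlation 0 of 14 stood, and with fry 6 did (nephron progenitor, early nephron, loop and distal tubule, proximal tubule, Notch pathway and stroma). The estimated correlation lay below the preset 0.01 for early nephron (-0.0187), nephron progenitor (-0.0103), the Notch pathway (-0.0366) and stroma (-0.0244). A higher correlation is therefore not why those calls were lost. With an estimated correlation camera takes its p value on the fit's 2 residual degrees of freedom, not on the number of genes. So few degrees of freedom raise the p value of the same statistic.

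**Figure D2:**
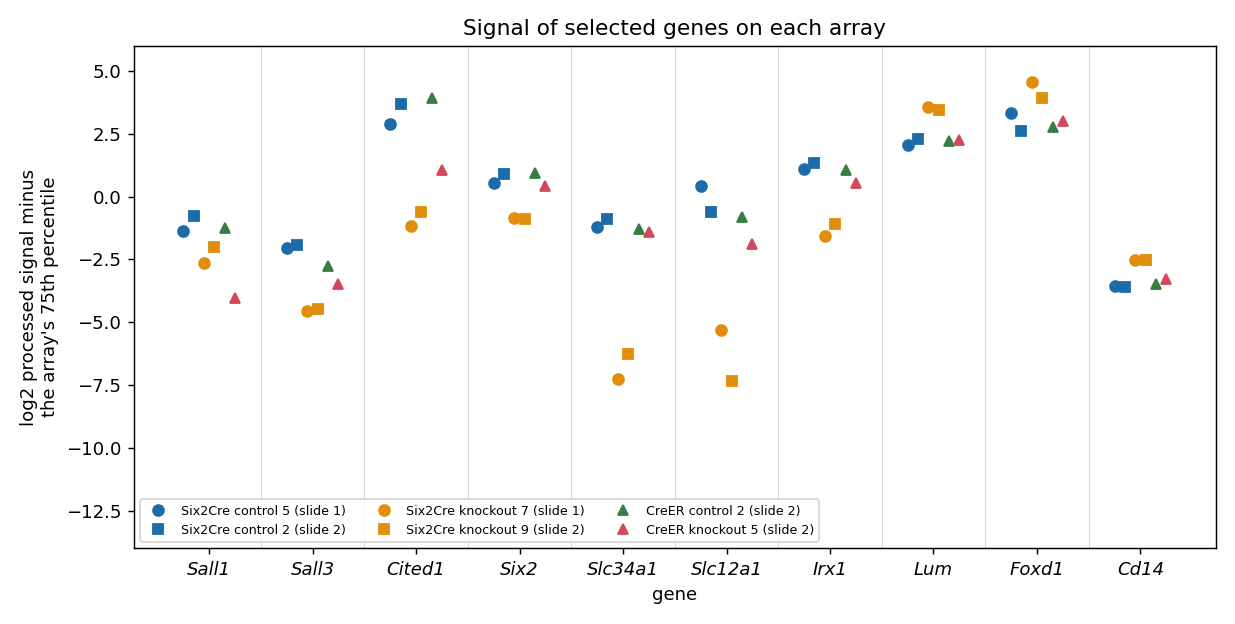
Log2 processed signal minus the array's 75th percentile for 10 genes, one point per array (Six2Cre controls blue, Six2Cre knockouts orange, CreER control green, CreER knockout red; circles are slide 1, squares and triangles slide 2). Sall1 and Cited1 were lower on the knockout array of every pair, and Slc34a1 was -5.71 in the Six2Cre contrast but -0.13 in the CreER pair.

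The CreER comparison asks what differs 48 hours after the deletion was induced. Sall1 (6.87-fold lower) and Cited1 (7.20-fold lower) were among the 10 largest differences below the control, with Ocm, which encodes oncomodulin (13.7-fold lower), Lamp5 (7.49-fold lower) and Sim2 (5.95-fold lower). Ccnb1ip1 was 6.42-fold, the adhesion gene Chl1 6.35-fold, Akr1c18 5.57-fold, Dync1i1 4.93-fold and Cadm3 4.78-fold lower. Among the 10 largest values above the control were those of Slc22a28 (19.9-fold higher), Tenm2 (13.0-fold), Hs3st2 (12.6-fold), Syt15 (10.9-fold), Olfr139 (10.8-fold), Slc5a12, a lactate transporter of the proximal tubule (10.2-fold), Nkx6-1 (8.57-fold), Slc22a30 (7.95-fold) and Myog (7.36-fold).

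The nephron progenitor list had a median of -0.24 in the CreER pair, below all 10000 random lists matched on signal, with 20 of 29 members lower. The loop and distal tubule list was at -0.50 with 16 of 17 members lower, and the early nephron list at -0.17 with 19 of 28 lower, both below all random lists. Posterior Hox genes were at -0.34 with 12 of 13 lower, below all random lists. By contrast, the proximal tubule list was at 0.23, above all random lists, with 19 of 28 members higher, and the podocyte list was at 0.15. The macrophage list was at 0.35 with 19 of 19 members higher, above all random lists, and the stroma list at 0.06. The muscle list was at 0.61, and on CreER knockout 5 its members lay a median of 1.503-fold above each gene's own median on the other 5 arrays. In all, 14 of the 26 lists lay in the outer 2.5% of the random lists on one side, muscle, erythroid, endothelium and hypoxia among them. The CreER arrays alone allow no test of a gene or list, and a CreER contrast that borrows the spread of the Six2Cre groups was not run.

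At least 2-fold differences were 358 higher and 576 lower of 25927 features in the CreER pair. The slide 1 Six2Cre pair had 815 and 2004, and the slide 2 pair 1344 and 824. Between arrays of one genotype, Six2Cre control 2 against control 5 on the other slide gave 986 higher and 2078 lower. Six2Cre knockout 9 against knockout 7 gave 2124 and 1034, and CreER control 2 against Six2Cre control 2, on the same slide but of different lines, gave 390 and 423. With normexp the CreER counts were 112 higher and 46 lower. Among features well above background on both arrays they were 292 and 95, a filter that drops features not well above background on the noisier knockout array.

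Over both lines, the genotype effect was read from 3 knockout and 3 control arrays. Cited1 had a log2 fold change of -3.72 and Sim2 of -3.19. The growth factor Fgf1 was -1.73, Dkk1 -1.83 and Sox8 -1.68. Fam167a was -2.14 and the serotonin receptor Htr5b -1.72. Higher were the adenylate cyclase Adcy8 (2.80), Kera (1.96), Anks1b (1.77), Rnf152 (1.66), Lrrc4c (1.59), the fibroblast protease Fap (1.49) and the chemokine Ccl21a (1.47). These 14 genes lay in one direction in each of the 3 pairs. They were picked by lowest p in a fit over the same pairs, so that agreement is no separate support. The other 6 genes of lowest p were dim on every array of at least 1 group, so only their Six2Cre folds are given. Cyp2a5 was at least 1.57-fold, Lcn2, which encodes lipocalin 2, at least 1.95-fold and the acetylcholine receptor subunit Chrna9 3.04-fold lower there. The recombinase Rag1 was at least 6.11-fold, Car10 at least 1.81-fold and Brinp3 4.05-fold higher. The adjusted p of all 20 over both lines was 0.207 and none passed. Over all features limma called 0 higher and 0 lower, with 1525 and 1040 at an unadjusted p under 0.05, where chance gives 1320 in all. That total of 2565 was 1489 without Six2Cre control 5 or without Six2Cre knockout 7. With normexp there were 16 and 20 calls, and with eBayes trend and robust 6 and 6.

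**Figure D3:**
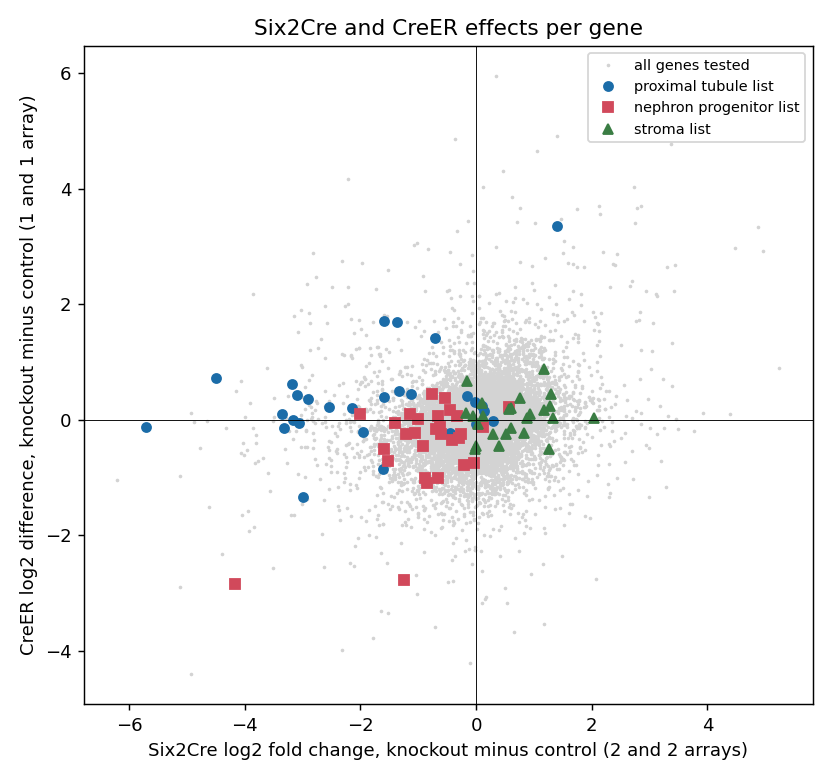
Log2 difference of each feature in the CreER pair (vertical axis, 1 and 1 array) against the Six2Cre log2 fold change (horizontal axis, 2 and 2 arrays), both knockout minus control, with the proximal tubule (circles), nephron progenitor (squares) and stroma (triangles) lists marked. Most proximal tubule members lie left of 0 on the horizontal axis and near 0 on the vertical axis, with medians of -1.60 and 0.23, and Pearson r over all features was 0.209.

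The difference between lines was tested directly. Six2Cre and CreER values correlated across genes with a Pearson r of 0.209 and a Spearman rho of 0.202, against a Pearson r of 0.390 between the Six2Cre pairs of the 2 slides. The slide 1 pair gave 0.228 with the CreER pair and the slide 2 pair 0.119. Genes at least 2-fold lower in both Six2Cre pairs, a set chosen after the data had been seen, had a CreER median of -0.27, and 71.2% of the 441 were lower. Genes at least 2-fold higher had a CreER median of 0.25, and 68.0% of the 412 were higher. Both medians lay beyond those of all 10000 random sets matched on signal. For single genes limma called 0 as different between lines, with 307 higher and 307 lower at an unadjusted p under 0.05, fewer than the 1320 that chance gives. This fit leaves the slide in the spread, and it recovered 0% of simulated 8-fold Six2Cre changes. Recovery of a difference between lines was not simulated. With slide as a block limma also called 0, with 1379 at an unadjusted p under 0.05. The 0 and the low count therefore do not show that the lines are alike. The slide block with eBayes trend and robust, chosen after the data had been seen, called 8: Slc34a1, Amn, Cyp2d26, Vil1, Gpx6, Hsd3b4 and Hsd3b5, less low or higher in the CreER line, and Chl1, the reverse. Apart from Slc34a1, Amn and Chl1, these were named after their values were seen.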

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

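The tests of explanations in this part, and the camera test of the lists between lines, were chosen after the results were seen. The results given here are 13 gene lists that passed camera on the difference between lines at the preset correlation. Their members share the error of single CreER arrays. With an estimated correlation, where camera uses the fit's 2 residual degrees of freedom, none of these lists passed (adjusted p from 0.182 to 0.599). The median over members of the CreER minus Six2Cre log2 difference was 2.05 for proximal tubule, 0.63 for early nephron, 0.52 for loop and distal tubule, 0.50 for nephron progenitor, 0.48 for the Notch pathway, 0.47 for FGF targets, 0.33 for Wnt targets and 0.27 for podocyte. It was 2.39 for muscle, 0.44 for erythroid, -0.54 for stroma, -0.36 for macrophage and -0.18 for hypoxia and glycolysis. At the preset correlation, adjusted p ran from 4.26e-39 for proximal tubule to 0.0451 for hypoxia and glycolysis. The muscle difference goes with the muscle transcripts on Six2Cre control 2, which lay a median of 14.6-fold above each gene's own median on the other 5 arrays. The erythroid difference goes with a low CreER control 2, whose list median was -0.93, against 0.03 to 0.59 on the other 5 arrays.

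The proximal tubule list was lower in both Six2Cre pairs and not in the CreER pair. CreER knockout 5 was the noisiest array, but the 18 members bright enough to show a fall above its floor had a CreER median of 0.27 (SD 0.13 over resampled members) against -1.60 in Six2Cre, which argues against dim spots hiding a fall. On slide 2, which held both lines, the CreER median lay 1.92 above the Six2Cre median, against a gap of 0.0877 between the Six2Cre pairs, which argues against the slide. Genes 2-fold lower in both Six2Cre pairs were at -0.27 on the CreER arrays, below the lowest of the random sets (-0.10), which argues against swapped CreER labels. The line and the time since deletion, which the design varies together, stay open as untested, and tubules formed before tamoxifen may carry these transcripts.

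Stroma and macrophage lists were higher in Six2Cre knockouts, with stroma at 0.60 and macrophage at 0.70. If a lower share of nephron cells raised every other cell type alike, these lists would match endothelium and erythroid lists. Stroma and macrophage members lay 0.64 above endothelium and erythroid members (medians 0.66 and 0.02). The permutation p was 1e-05, the smallest that the permutations can give, over genes that are not independent. Outside the nephron, ureteric trunk was also higher (0.50) and ureteric bud tip lower (-0.35), and the erythroid median ran from -0.18 to 0.20 with 1 array left out. The values speak only against an equal rise, and a lower share of nephron cells cannot be set aside as part of it. Connective tissue carried with the muscle on Six2Cre control 2 would raise a list in a control, and so lower it in knockouts. It could not give this pattern, so the slide 1 pair is no test of it. That pair, which lacks Six2Cre control 2, shows only that the rise was present without that array (lower of the 2 medians 0.60). A change in the number or state of stromal cells and macrophages stays open as an untested hypothesis.

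Six3, the gene next to Six2, was chosen after its values were seen. It was well above background on both Six2Cre knockout arrays and on no control or CreER array, at least 12.46-fold higher than in Six2Cre controls (adjusted p = 0.169). The Six2Cre knockout mean lay 2.17 log2 units above the bound for the CreER knockout array, at least 4.51-fold. A copy of the region carried with the Cre transgene is a candidate explanation. It cannot be told apart from an effect of Sall1 loss, because the labels do not say whether the Six2Cre controls carry Cre. Other measured genes of the region were not higher to that extent (Prepl 0.20, Prkce -0.41, Epas1 -0.29, Slc3a1 -0.70), which a short copy would allow. Six3 was not well above background on either CreER array, so no fold is given for the CreER pair.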

How the results depend on the processing

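Combinations of the slide block with another choice, the values within a slide, and the counts among features well above background on both CreER arrays were chosen after the data had been seen; the other settings were planned. Of 122 alternatives for the main values and counts, 102 kept the result and 20 moved it. Many of those kept set a count of 0 calls against another count of 0, and 1 repeats the only Sall1 probe. The share kept is therefore no measure of robustness. Six2Cre counts higher and lower were 325 and 336 with the slide block and eBayes trend and robust, 225 and 262 with the block and normexp, 100 and 182 with the block and the filter on all 6 arrays, and 13 and 56 at adjusted p under 0.1; they were 0 and 0 in all the other settings run, the block with quantile normalization, no filter, the mean of probes or series values included. Counts over both lines were 16 and 20 with normexp and 6 and 6 with eBayes trend and robust. The count at an unadjusted p under 0.05 over both lines was 2565 as reported, 1489 without either Six2Cre array of slide 1, 1606 without either Six2Cre array of slide 2 and 3073 without either CreER array. The difference between lines gave 8 with the block and trend and robust. CreER counts higher were 112 with normexp and 4407 with no filter; those lower were 46 with normexp, 93 with the filter on all 6 arrays and 95 among features well above background on both arrays. The higher share of the CreER 2-fold features was 38.3% as reported, 70.9% with normexp, 87.4% with no filter and 72.5% with the filter on all 6 arrays. No scaling moved the median of all features by more than 0.1. Lists called numbered 0 with an estimated correlation, where camera uses 2 residual degrees of freedom, and 6 with fry. Dropping the filter or requiring all 6 arrays changes which features are counted. Beyond these points the cause was not tested.

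Of 2772 alternatives for named genes, 2586 kept the result, 152 passed the threshold where the reported fit did not, 18 moved and 16 changed sign. No named gene passed in the reported fits. For a tested gene, kept therefore means the same sign and again no pass, whatever the size of the change. Of 312 alternatives for lists, 252 kept the result, 30 lost the call, 5 gained it, 13 moved and 12 turned the direction of the test or the sign. The muscle median was 0.29 within slide 1, and Dazl was 0.0666 with the mean of its probes. Leaving out each array in turn gave list medians from 0.0393 to 0.18 for endothelium, -0.18 to 0.20 for erythroid, -0.45 to 0.21 for gonad and germ cells, -0.0843 to 0.11 for hypoxia and glycolysis, -0.0387 to 0.18 for immediate early stress and -0.0439 to 0.20 for p53 and apoptosis. It kept the sign but moved the median by over 1.5 times for adrenal (-0.58 to -0.0857), BMP and TGF-beta (-0.27 to -0.13), podocyte (-0.66 to -0.38), posterior Hox (-0.30 to -0.065), proliferation (-0.22 to -0.0589), Sall proteins with NuRD (-0.26 to -0.0652), ureteric bud tip (-0.54 to -0.18), ureteric trunk (0.23 to 0.58), Wnt targets (-0.57 to -0.30) and the measured Y-linked genes (0.0954 to 0.41). Muscle ran from -3.79 to 0.0348 and neural crest from -0.31 to 0.0085. It gave log2 fold changes from -0.0305 to 0.52 for Sall4, -1.98 to 0.43 for Hsd3b1, -2.28 to 0.61 for Fst, -1.44 to 0.68 for Flt1, -1.03 to 0.0045 for Gata1, -5.95 to 0.40 for Myh3, -0.48 to 1.40 for Hdac2, -0.31 to 0.88 for Uty, -0.0191 to 0.52 for Kdm5d and -0.0903 to 0.21 for Ddx3y. The Sall1 value ran from -1.57 to -0.92. The values without 1 array also ranged widely for Sall2 (-0.32 to -0.0757), Chd4 (-0.80 to -0.35), Dazl (-1.20 to -0.12), Nphs1 (-4.93 to -2.09), Slc12a1 (-7.21 to -5.19), Etv4 (-1.81 to -0.58), Foxi1 (-2.30 to -0.87), Upk1b (0.36 to 2.04), Adamts18 (0.56 to 1.97), Ttn (-6.29 to -1.44), Myog (-4.57 to -1.07) and Tnnt2 (-4.22 to -0.37). By replicate number, no paired analysis was possible because the Six2Cre groups share none; arrays were paired by slide instead, through the slide block and the values within each slide. Signal over background limits the dim features, most of all on CreER knockout 5.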

Other observations

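The list values of the CreER pair and the count of splits in this part were planned, and the choice of which lists to describe was made after the data had been seen. In the CreER pair, erythroid transcripts were higher on the knockout array for 13 of 13 members, with a median difference of 0.75, above all 10000 random lists matched on signal. It was the control array that stood apart: the median erythroid level was -0.93 on CreER control 2, 0.03 on CreER knockout 5 and between 0.11 and 0.59 on the Six2Cre arrays. The embryonic globin Hbb-y was 3.68 on CreER control 2 and between 4.35 and 5.18 on the other 5 arrays. Endothelial transcripts were higher for 18 of 20 members, with a median of 0.24. Hypoxia and glycolysis transcripts were lower for 19 of 20 members, with a median of -0.25, among them Eno1 (-0.53) and Adm, which encodes adrenomedullin (-0.41). These are values of single arrays, with no test. In the Six2Cre comparison the same lists had medians of 0.12, 0.02 and 0.03, and none passed.

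For the genotype effect over both lines, the 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 features at adjusted p under 0.05 in each direction and the highest of the others also gave 0; against a real count of 0, all 10 splits give as many by construction, so the count says nothing about chance. At an unadjusted p under 0.05 the real split gave 2565 features and the others from 485 to 3159. The real count was 1489 without Six2Cre control 5 or without Six2Cre knockout 7. The 2 splits with 3159 part only the slide 1 Six2Cre pair once line and slide are fitted.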
